A study of Danio rerio with 12 samples.

How the data were processed

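RNA of 24-hour zebrafish embryos (1 to 3 embryos per library) was turned into libraries with a 3' tag kit that reads from the polyadenylated end of messenger RNA (QuantSeq, forward version) and was sequenced on an Illumina NextSeq, per the labels' protocols. Spike-in RNAs were added at a low level, per the labels' protocols, and are not used here. Reads were aligned with STAR and compared with edgeR on the genome build GRCz11, also called danRer11, per the submitters' processing notes. Versions, settings, the counting program, the use of strand and the design of the edgeR comparison are not given in the sources used here.

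The authors deposited 1 table of 13680 genes with 12 library columns, their log2 fold change and their FDR. Per the file headers, the log2 column is the authors' log2 fold change, and its sign, checked against the library columns, is offspring of starved fathers over offspring of fed fathers. The deposited FDR is the authors' adjusted p-value, and their class column calls genes at an FDR below 0.1 (tested on the table). The deposited library values are an expression signal: read counts divided by a size factor for each library, rounded to 2 decimals, with sums between 781030 and 1229200 per library. This was found from the values, since no header names the unit. Within a library the values are whole multiples of what 1 read is worth (0.234 to 0.374), and 100% of the values came within 0.03 of a whole read, with a largest deviation of 0.0216. Whole reads were recovered in this way, 2950739 to 3934765 per library over the listed genes. Only genes above a filter of the authors, whose rule is not given in the sources used here, are listed, so reads of other genes are outside these totals. Library columns of other series were 0. Gene coordinates are those of the table, in GRCz11.

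Libraries were assigned to 6 fed fathers' and 6 starved fathers' offspring from their titles, and table columns to libraries by their descriptions. No pair of libraries of a group was a duplicate: over the 30 pairs within groups, the chi-square of recovered reads per degree of freedom lay between 6.33 and 40.6 for genes with at least 10 reads in the pair. The tests, gene lists, rule for named genes and a list of other settings were fixed before the data were examined. The first choice was edgeR's quasi-likelihood test on counts, with limma in its place where the table held a normalized unit, which was the case. The comparison was therefore made with limma 3.58.1 in R 4.3.3 (moderated statistics with a trend of the variance on the mean) on log2(value + 1), without a block, over all 13680 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences on this scale understate the change of low genes. Gene lists (34, of which 33 had at least 5 measured members) were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 33 lists. The result of 1 of these lists and the values of 2 genes are not reported here. No list was called with an estimated correlation (smallest adjusted p = 0.918) or with fry, which asks whether a list's genes move on balance one way (smallest adjusted p = 0.849). Enrichment of lists among the calls of the authors' deposited table was tested with Fisher's exact test, two-sided, against all listed genes. Library scores of lists were compared by exact permutation over all 924 arrangements of the 12 libraries.

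The count tests on recovered reads (edgeR 4.0.16 with TMM, limma-voom, DESeq2 1.42.0) were alternatives. DESeq2 left the adjusted p of 3 genes empty, which stayed so. Other alternatives were pseudocounts of 0.5 and 5, a minimum mean value of 5, other thresholds, blocks on the replicate number or on the description code, replicates 5 and 6 summed, each library left out in turn, and pairs of libraries left out. On simulated counts for the 13680 genes of the comparison of starved with fed fathers, limma recovered 27% of 100 genes changed 2-fold and 73% of 100 genes changed 4-fold, with 8 false calls, and edgeR 28% and 73%, with 9 false calls. Genes were simulated independently of each other and without an effect shared within description codes, so these rates may not hold for the real libraries.

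Named genes were the 12 with the smallest p on each side among those past the threshold. Where fewer than 5 passed on a side, the 8 with the smallest unadjusted p were given and said not to pass. Up to 4 members with the smallest p were taken from each list, and the rule for passing genes was applied to the FDR of the authors' deposited table. Clone-style names were left out. Gene names are those of the table; 13388 of the 13680 identifiers were also found in a reference list of names, used only for clone-style names. Names shared by several identifiers (105 repeats) and families of near-identical genes, among them crystallins, globins, histones, fast myosins, her4 and her15 genes, are uncertain where reads of copies were split. The same holds for overlapping and antisense genes, since the use of strand in counting is not stated.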

Results

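The series asked whether starving male zebrafish before fertilisation leaves a trace in the gene expression of their offspring. Sperm of fed or of starved males was used to fertilise eggs of fed wild-type females in vitro, and the embryos, of the AB laboratory strain, were frozen at 24 hours after fertilisation. At that age the body axis, the beating heart and striated muscle are already formed and the yolk is still large. Each library was made from 1 to 3 embryos of a clutch. The transcripts were measured by 3' RNA sequencing, in which reads start near the polyadenylated end of a transcript, so that a read stands for a transcript irrespective of its length. There were 6 libraries of offspring of fed fathers and 6 of offspring of starved fathers. The labels do not say whether each library came from its own father, and replicates 5 and 6 of both groups share a description code, so the p-values measure the spread between these libraries.

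The table covered 13680 genes. The whole reads behind its values came to between 2950739 and 3934765 per library. The mean was 3427709 ± 217700 in offspring of fed fathers and 3352401 ± 327994 in offspring of starved fathers (SD, n = 6 each, two-sided exact permutation p = 0.656). The most abundant transcript was ENSDARG00000080337, on the mitochondrial chromosome from base 2043 to base 3725 (build GRCz11), where the large ribosomal RNA gene of the mitochondrion lies. It took between 27.0% of the reads in starved replicate 3 (95% exact Clopper-Pearson interval 26.9 to 27.0) and 48.7% in fed replicate 5 (48.7 to 48.8). The mean share was 42.0 ± 5.90% in offspring of fed fathers and 37.7 ± 6.42% in offspring of starved fathers (SD, n = 6 each), a difference within the spread between libraries (two-sided exact permutation p = 0.255). These intervals cover counting error only.

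Offspring of starved fathers had lower mean values of the cathepsin genes ctss2.1 and ctsba, the lysosomal transporter gene spns1 and the metabolic genes dbi and sord, and higher mean values of the muscle gene klhl31 and the neuronal gene insm1a, but neither these nor other genes passed limma's test without a block. With limma on log2 values, 0 of 13680 genes passed an adjusted p below 0.05, and the smallest adjusted p was 0.775. At an unadjusted p below 0.05 there were 758 genes, 288 of them higher and 470 lower in offspring of starved fathers, where chance gives 684. On the whole reads behind the values, edgeR's quasi-likelihood test, limma-voom and DESeq2 each called 0 genes, with 634, 761 and 754 genes at an unadjusted p below 0.05. Some fits with a block did call genes, and their counts stand with the other settings. With the replicate number as a block limma called 39 genes, 8 higher and 31 lower. Below, a gene is said to pass or not in the test without a block unless a block is named. The values of the 6 libraries of one group all lay beyond those of the other for 32 genes, 15 higher and 17 lower, where chance gives 29.6 genes (0.216%). The authors' deposited table, which holds their own edgeR comparison, lists 105 genes at an FDR below 0.05, 20 of them higher and 85 lower in offspring of starved fathers, and 145 (30 and 115) at the FDR below 0.1 that its class column uses. All 105 had the same direction in the limma comparison, and 81 of them had an unadjusted p below 0.05 there. Both comparisons used the same 12 libraries, so this gives no independent support.

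The genes with the smallest p among those lower in offspring of starved fathers, none of which passed, were msx1b, hao2, ctsba, dbi, sord, ctss2.1, selenop and spns1. The homeobox gene msx1b (chromosome 1, bases 49352900 to 49355313, GRCz11) had a value of 11 ± 4.5 in offspring of fed fathers and 3.28 ± 2.32 in offspring of starved fathers (SD, n = 6 each), a log2 difference of -1.52 ± 0.35 (SE). The oxidase gene hao2 was at 6.03 ± 3.02 and 1.26 ± 0.78, with every library of starved fathers below every library of fed fathers, and sord, which encodes sorbitol dehydrogenase, was at 5.91 ± 3.22 and 1.18 ± 0.77. Both rest on few reads per library, 7 to 32 (fed) and 1 to 8 (starved) for hao2 and 6 to 30 and 1 to 9 for sord. The acyl-CoA-binding protein gene dbi was at 146 ± 40.5 and 82.9 ± 23.6, and selenop, which encodes a selenium-carrying plasma protein, at 259 ± 76.6 and 141 ± 48.8 (SD, n = 6 for each of these). Adjusted p was 0.775 with limma without a block for all 8. For each of them all 6 libraries of starved fathers lay below the mean of the libraries of fed fathers, which picking genes by their smallest p makes likely. With the replicate number as a block at least ctss2.1, ctsba and spns1 passed, as the next paragraph gives.

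In the authors' deposited table the lowest FDR among the lower genes belonged to ctss2.1, a cathepsin S gene (log2 fold change -2.21, FDR 6.03e-17). It was followed in the authors' deposited table by ctsba, a cathepsin B gene (-1.12, FDR 3.73e-07), acp5a, an acid phosphatase gene (-1.31, FDR 1.13e-06), npc2, which encodes a cholesterol-binding protein of lysosomes (-1.15, FDR 1.63e-06), and spns1, which encodes a lysosomal membrane transporter (-1.70, FDR 1.81e-06). Further lower genes of the authors' deposited table were the apolipoprotein genes apoa1b (-0.94, FDR 1.81e-06) and apoc1 (-0.88, FDR 1.21e-05), selenop2 (-1.42, FDR 1.78e-05), apoa2 (-0.83, FDR 6.23e-05), the myosin light chain gene myl12.1 (-0.96, FDR 7.55e-05) and ndufs6, a subunit of respiratory complex I (-1.32, FDR 0.000204). From the library values, ctss2.1 (chromosome 16, bases 29509133 to 29513434) was at 52.7 ± 48.4 in offspring of fed fathers and 11.2 ± 8.14 in offspring of starved fathers (SD, n = 6 each), with a limma log2 difference of -1.90 ± 0.47 (SE). Its 2 highest values were 131 in fed replicate 5 and 94.0 in fed replicate 4. For acp5a the means were 56.9 ± 41.9 and 22.9 ± 12.8, for npc2 119 ± 81.8 and 52.2 ± 20.9, and for spns1 25.7 ± 17.5 and 8.77 ± 6.78 (SD, n = 6 each). With the replicate number as a block, a pairing that the labels do not state, the genes named in this paragraph passed limma's test. Their adjusted p ran from 0.000497 (ctss2.1) to 0.0441 (ndufs6).

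Genes of yolk lipoproteins and the yolk syncytial layer, the tissue that breaks down yolk and exports its lipid, were lower as a group. Of the 34 members measured, 33 had a lower and 1 a higher mean log2 value in offspring of starved fathers, with a median log2 difference of -0.53 (camera with a preset correlation, adjusted p = 2.62e-08), but adjusted p = 0.918 with an estimated correlation. Without a block, no member passed over all genes tested, and 8 passed when adjusted over the list alone. With the replicate number as a block, a pairing that the labels do not state, members did pass over all genes. Among these were apoa1b (limma, adjusted p = 0.00507) and apoc1 (0.0274). Apolipoprotein apoc1 (chromosome 16, bases 23972126 to 23973721) was at 1875 ± 703 in offspring of fed fathers and 1070 ± 445 in offspring of starved fathers (SD, n = 6 each; log2 difference -0.87 ± 0.27, SE). The protease gene ctsba (chromosome 17, bases 32622931 to 32631514) was at 268 ± 118 and 128 ± 51.4 (-1.08 ± 0.26), mttp, the microsomal triglyceride transfer protein that loads lipoproteins with lipid, at 52.0 ± 20.5 and 28.2 ± 18.8 (-1.0 ± 0.32), and the fibrinogen gene fga at 38.3 ± 15.6 and 20.3 ± 4.77 (-0.83 ± 0.24). Of the 34 members, 13 were lower and 0 higher at an FDR below 0.05 in the authors' deposited table (Fisher's exact test against all listed genes, adjusted p = 4.35e-19). Fisher's test takes genes as independent, while the estimated correlation between yolk genes was 0.52. Its p-value therefore does not measure the spread between libraries. The list score, the mean over members of the log2 values centred per gene, was 0.27 ± 0.62 in offspring of fed fathers and -0.27 ± 0.46 in offspring of starved fathers (SD, n = 6 each, two-sided exact permutation p = 0.128), and 5 of 6 libraries of starved fathers lay below the mean of the fed group. The highest scores were 1.08 in fed replicate 5 and 0.88 in fed replicate 4. Without these 2 libraries, but with starved replicates 4 and 5 kept, the median was -0.175 (camera, adjusted p = 0.327).

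Skeletal muscle genes were higher as a group. Of 63 members, 53 had a higher and 10 a lower mean log2 value in offspring of starved fathers, with a median log2 difference of 0.35 (camera, adjusted p = 6.38e-08), but adjusted p = 0.918 with an estimated correlation. Without a block, no member passed, over all genes or adjusted over the list alone. With the replicate number as a block, tnnt3b (limma, adjusted p = 0.00683) and myhz1.2 (0.0233) passed over all genes, while ttn.1 (0.104) and tnni2a.4 (0.104) did not. The slow myosin heavy chain gene smyhc1 (chromosome 24, bases 40656510 to 40668208) was at 570 ± 171 in offspring of fed fathers and 834 ± 85.7 in offspring of starved fathers (SD, n = 6 each; log2 difference 0.60 ± 0.18, SE). A second slow myosin gene, smyhc2, was at 20.7 ± 5.98 and 30.8 ± 6.87, the tropomyosin gene tpm2 at 174 ± 16.5 and 229 ± 37.0, and the myosin light chain gene myl10 at 326 ± 43.5 and 413 ± 34.2. The muscle list score was -0.17 ± 0.63 in offspring of fed fathers and 0.17 ± 0.40 in offspring of starved fathers (SD, n = 6 each, two-sided exact permutation p = 0.268), with 5 of 6 libraries of starved fathers above the mean of the fed group. The lowest scores were -1.13 in fed replicate 4, -0.73 in fed replicate 5 and -0.55 in starved replicate 4. Without fed replicates 4 and 5, but with starved replicate 4 kept, the median turned to -0.05 (camera, adjusted p = 0.977).

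**Figure D1:**
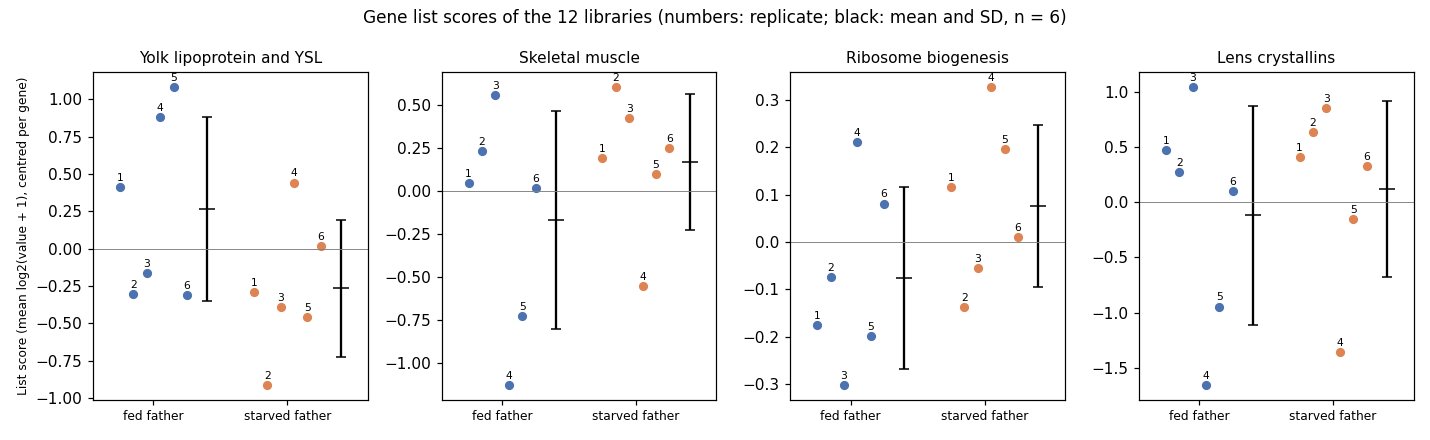
Scores of 4 gene lists in the 12 libraries, by group of fathers; the y axis is the mean over a list's members of log2(value + 1) centred per gene, points are libraries labelled by replicate number, and black marks are the mean and SD of 6 libraries (YSL, yolk syncytial layer). Fed replicates 4 and 5 had the highest yolk scores (0.88 and 1.08) and the lowest muscle scores (-1.13 and -0.73), and the groups overlapped in each list.

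Of the 63 muscle genes, 10 were higher and 0 lower at an FDR below 0.05 in the authors' deposited table (Fisher's exact test against all listed genes, adjusted p = 1.19e-17). Of the 66 such tests, over 33 lists and both directions, only this one and that of lower yolk genes passed, and the smallest adjusted p of the others was 0.369. Fisher's test takes genes as independent, while the estimated correlation between muscle genes was 0.42. Its p-values therefore do not measure the spread between libraries. Among the 12 genes with the smallest FDR on the higher side of the authors' deposited table were the fast troponin genes tnnt3b (log2 fold change 0.80, FDR 0.000812), tnni2a.4 (0.65, FDR 0.0206) and tnnt3a (0.63, FDR 0.023). The authors' deposited table also listed there the titin genes ttn.2 (0.71, FDR 0.000925) and ttn.1 (0.63, FDR 0.00695) and the fast myosin heavy chain genes myhz1.2 (0.83, FDR 0.00125) and myhz1.3 (0.71, FDR 0.00161). From the library values, ttn.2 (chromosome 9, bases 42894845 to 43073960) was at 2399 ± 1535 in offspring of fed fathers and 3309 ± 925 in offspring of starved fathers, and myhz1.3 (chromosome 5, bases 32262499 to 32274383) at 740 ± 396 and 1119 ± 312 (SD, n = 6 each). The myosin genes lie side by side as similar copies, so the split of reads between them is uncertain. The other genes of the authors' deposited table on that side were fosab (3.23, FDR 1.74e-16), the embryonic globin gene hbbe1.1 (1.18, FDR 2.24e-06), the histone H4 gene hist1h4l (0.78, FDR 0.00235), klhl31 (0.77, FDR 0.00305) and the crystallin gene crygn2 (0.84, FDR 0.023). Globin and histone genes also have near-identical copies, and their values carry the same uncertainty.

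The transcription factor gene fosab, an immediate early gene that cells switch on within minutes of a stimulus, was high in 2 of the 6 libraries of starved fathers. Its value was 356 in starved replicate 2 and 67.6 in starved replicate 5, against 0.48 to 2.57 in the other 4 libraries of starved fathers and 0.29 to 6.85 in the 6 libraries of fed fathers. The limma log2 difference was 1.87 ± 0.95 (SE, adjusted p = 0.885). The histone gene hist1h4l was at 142 ± 38.8 in offspring of fed fathers and 290 ± 216 in offspring of starved fathers (SD, n = 6 each), with its highest value, 701, also in starved replicate 2. The globin gene hbbe1.1 was at 54.6 ± 44.0 and 103 ± 59.7.

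The 8 genes with the smallest p among those higher in offspring of starved fathers, none of which passed, were insm1a, klhl31, dsg2.1, RIC1, psmd13, fxr1, rhoab and ap1g2 (limma adjusted p = 0.775 for each). The zinc finger gene insm1a (chromosome 20, bases 48482925 to 48485354), which is active in differentiating neurons and endocrine cells, was at 7.87 ± 1.71 in offspring of fed fathers and 16.0 ± 2.66 in offspring of starved fathers (SD, n = 6 each; log2 difference 0.94 ± 0.24, SE). The kelch family gene klhl31, expressed in muscle, was at 121 ± 45 and 198 ± 35.3 (0.77 ± 0.20). The proteasome subunit gene psmd13 was at 58.0 ± 6.05 and 86.3 ± 15.3, with no overlap between groups. The desmosomal cadherin gene dsg2.1 also showed no overlap, at 1.02 ± 0.67 and 4.19 ± 2.02, which rest on 1 to 7 reads and on 8 to 35 reads per library. The RNA-binding protein gene fxr1 was at 36.2 ± 9.07 and 56.8 ± 10.7, and the small GTPase gene rhoab at 46.0 ± 6.04 and 69.0 ± 12.9. RIC1 (0.66 ± 0.64 and 3.02 ± 1.06) and the clathrin adaptor gene ap1g2 (1.1 ± 0.61 and 3.79 ± 1.40) were close to the floor, with at most 7 reads in any library of fed fathers. All 6 libraries of starved fathers lay above the mean of the fed group for each of the 8 genes, which picking genes by their smallest p makes likely. With the replicate number as a block at least klhl31 passed (limma, adjusted p = 0.0154).

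**Figure D2:**
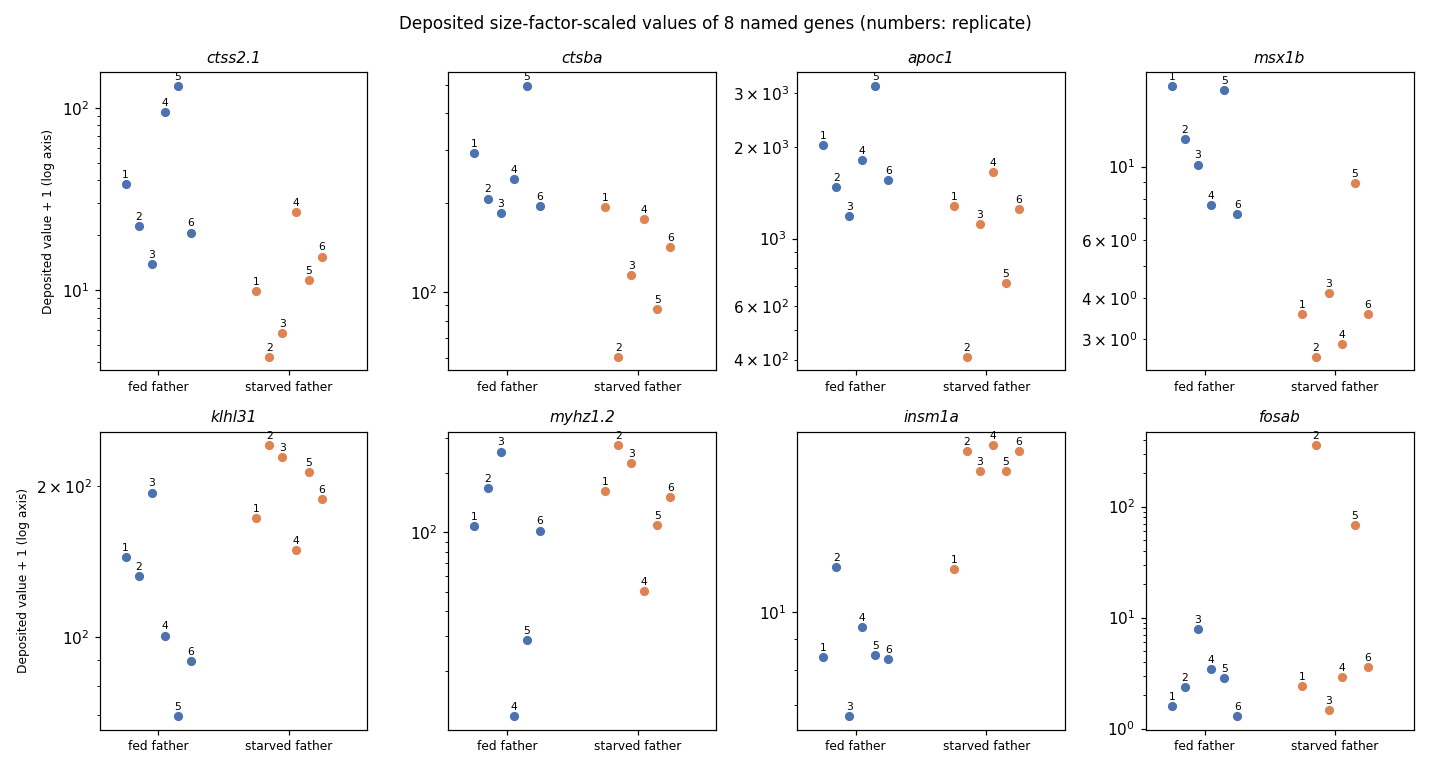
Deposited values of 8 named genes in the 12 libraries, by group of fathers; the y axis is the size-factor-scaled value plus 1 on a log scale, and points are libraries labelled by replicate number. The values of fosab reach 356 and 67.6 in starved replicates 2 and 5 and stay at or below 6.85 in the other libraries, while insm1a averages 7.87 in offspring of fed fathers and 16.0 in offspring of starved fathers.

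Ribosome biogenesis genes, which build ribosomes in the nucleolus, were the third list with a call. Of 48 members, 42 had a higher and 6 a lower mean log2 value in offspring of starved fathers, with a median log2 difference of 0.17 (camera, adjusted p = 0.000423), but adjusted p = 0.918 with an estimated correlation. The call ended without starved replicate 4 (adjusted p = 0.0759). No member passed, over all genes or adjusted over the list alone, and the authors' deposited table calls 0 of them. The bystin gene bysl was at 51.9 ± 7.04 in offspring of fed fathers and 70.0 ± 7.41 in offspring of starved fathers (SD, n = 6 each), wdr12 at 19.1 ± 3.05 and 25.9 ± 2.92, bop1 at 70.4 ± 8.75 and 88.1 ± 12.8, and pes at 121 ± 24.0 and 152 ± 29.6. The list score was -0.08 ± 0.19 and 0.08 ± 0.17 (two-sided exact permutation p = 0.177). The 82 genes of cytosolic ribosomal proteins had a median log2 difference of -0.03, with 34 higher and 48 lower (camera, adjusted p = 0.50), among them rplp2 at 767 ± 119 and 576 ± 114.

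Lists of energy metabolism showed no call. The 32 glycolysis genes had a median log2 difference of 0.11 (17 higher, 15 lower; camera, adjusted p = 0.615). For pgk1 the values were 8.87 ± 4.34 in offspring of fed fathers and 3.27 ± 2.09 in offspring of starved fathers and for pfklb 2.67 ± 1.65 and 6.76 ± 3.21 (SD, n = 6 each). The 17 genes of gluconeogenesis and glycogen had a median of -0.15 (6 higher, 11 lower; adjusted p = 0.383). For the phosphoglucomutase gene pgm1 the values were 23.9 ± 10.8 and 12.8 ± 8.76. The 27 genes of the TCA cycle had a median of -0.04 (11 higher, 16 lower; adjusted p = 0.630). For sdhc the values were 37.8 ± 9.97 and 22.9 ± 11.3. Nuclear genes of oxidative phosphorylation, 75 in all, had a median of 0.00 and a mean of -0.04 (38 higher, 37 lower; adjusted p = 0.903). Among them atp5pd was at 151 ± 40.9 and 94.5 ± 30.9, ndufs6 at 29.6 ± 14.0 and 13.5 ± 8.48, and atp5f1b at 592 ± 91.4 and 739 ± 54.7. The 12 measured protein-coding genes of the mitochondrial genome had a median of -0.03 (6 higher, 6 lower; adjusted p = 0.903). For mt-co1 the values were 2071 ± 214 and 1781 ± 545. The 39 genes of fatty acid oxidation and ketone bodies had a median of -0.02 (17 higher, 22 lower; adjusted p = 0.533). For the lipid droplet gene plin2 the values were 2.45 ± 2.08 and 0.29 ± 0.46. The 26 genes of fatty acid and sterol synthesis had a median of -0.12 (11 higher, 15 lower; adjusted p = 0.473). For dhcr7 the values were 24.0 ± 10.3 and 16.6 ± 8.93. In each of these lists 0 members passed, over all genes or adjusted over the list alone. The authors' deposited table lists pgm1 (FDR 0.0136), sdhc (0.0458), atp5pd (0.0201) and ndufs6 (0.000204) as lower at an FDR below 0.05. With the replicate number as a block ndufs6 passed limma's test (adjusted p = 0.0441).

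Nutrient, hormone and stress lists showed no call either, and 0 of their members passed over all genes or adjusted over the list alone. Genes of insulin, IGF and FOXO signalling (30 members) had a median log2 difference of -0.10, with 9 higher and 21 lower (camera, adjusted p = 0.533), among them pik3ip1 at 5.45 ± 2.90 in offspring of fed fathers and 2.68 ± 1.84 in offspring of starved fathers and igfbp1a at 5.55 ± 2.53 and 3.79 ± 3.73 (SD, n = 6 each). For the glucocorticoid response (16 members) the median was -0.07, with 6 higher and 10 lower (adjusted p = 0.865). The gene hsd11b2, which inactivates cortisol, was at 5.18 ± 2.18 and 2.90 ± 1.40. For the amino acid and integrated stress response (34 members) the median was -0.05 although camera gave a higher rank (16 higher, 18 lower; adjusted p = 0.994). Heat shock genes (23 members) had a median of 0.08, with 15 higher and 8 lower (adjusted p = 0.347), and hsp90aa1.1 was at 365 ± 58.4 and 493 ± 114. Genes of endoplasmic reticulum stress (24 members) had a median of -0.14, with 7 higher and 17 lower (adjusted p = 0.360). The chaperone gene calr3a was at 310 ± 32.4 and 246 ± 45. Oxidative stress genes (31 members) had a median of -0.05, with 12 higher and 19 lower (adjusted p = 0.994). The gene nqo1 was at 68.4 ± 27.4 and 49.3 ± 15. Innate immune and interferon genes (17 members) had a median of -0.20, with 6 higher and 11 lower (adjusted p = 0.791). The gene stat1a was at 14.9 ± 3.80 and 10.6 ± 3.01. Of the lists in this paragraph, only oxidative stress held a call of the authors' deposited table, 1 lower gene at an FDR below 0.05.

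With all 12 libraries and no block, markers of other embryonic tissues differed by less than the camera test requires. Lens crystallins, which accumulate as the lens differentiates, had a median log2 difference of 0.28 over 28 members (19 higher, 9 lower; adjusted p = 0.218), and their scores were lowest in fed replicate 4 (-1.66), starved replicate 4 (-1.36) and fed replicate 5 (-0.95), libraries that also had the lowest muscle scores. The crystallin list was called without fed replicate 1 (adjusted p = 0.0178), fed replicate 3 (0.000612) or starved replicate 4 (3.99e-05) and with the description codes as a block (0.0157), but adjusted p = 0.816 to 0.914 with an estimated correlation in these settings. Without fed replicates 4 and 5 the median turned to -0.34 and the list was called lower (adjusted p = 0.0328, but adjusted p = 0.995 with an estimated correlation). Starved replicate 4, also with a low score, stayed in that fit. The crystallin gene crygn2 was at 25.4 ± 16.8 in offspring of fed fathers and 42.6 ± 18.3 in offspring of starved fathers (SD, n = 6 each). All 10 hatching gland genes had a lower mean (median -0.29; adjusted p = 0.331), and the highest scores of this list were 1.09 in fed replicate 5 and 0.64 in fed replicate 4. The 18 heart genes had a median of -0.23 (4 higher, 14 lower; adjusted p = 0.318). For tnnt2a the values were 24.5 ± 8.90 and 17.4 ± 8.54. The 24 endothelial genes had a median of 0.05 and a mean of 0.00 (13 higher, 11 lower; adjusted p = 0.922). For tie1 the values were 6.40 ± 3.35 and 9.78 ± 2.60. The 32 erythroid genes had a median of 0.01 and a mean of -0.07 (17 higher, 15 lower; adjusted p = 0.802). For the carbonic anhydrase gene cahz the values were 12 ± 5.8 and 5.06 ± 3.73. The 62 genes of neural progenitors and neurons had a median of 0.03 and a mean of -0.01 (34 higher, 28 lower; adjusted p = 0.664), and 1 member, insm1a, passed when adjusted over the list alone. In this list ascl1b was at 8.83 ± 3.58 and 3.67 ± 3.85 and vamp2 at 26.6 ± 6.64 and 39.0 ± 9.86.

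Among the remaining tissue lists, the 23 pigment cell genes had a median log2 difference of -0.01 (10 higher, 13 lower; camera, adjusted p = 0.664). For tspan36 the values were 32.0 ± 8.43 in offspring of fed fathers and 22.0 ± 9.97 in offspring of starved fathers (SD, n = 6 each). The 41 genes of periderm and epidermis had a median of -0.11 (14 higher, 27 lower; adjusted p = 0.360), and adjusted p = 0.0319 without fed replicate 6, but adjusted p = 0.725 with an estimated correlation there. For the claudin gene cldne the values were 57.0 ± 22.3 and 34.2 ± 10.9. The 23 genes of notochord and cartilage matrix had a median of -0.02 although camera gave a higher rank (11 higher, 12 lower; adjusted p = 0.952). For col8a1a the values were 19.4 ± 13.1 and 7.54 ± 4.41. The 26 genes of somitogenesis and tailbud had a median of -0.10 (9 higher, 17 lower; adjusted p = 0.664). For hes6 the values were 50.4 ± 18.6 and 71.0 ± 21.5. The 32 genes of the circadian clock and light response had a median of 0.01 (17 higher, 15 lower; adjusted p = 0.50). For nr1d2b the values were 3.04 ± 1.66 and 6.53 ± 2.90. The 9 genes of germ cells and maternal transcripts had a median of -0.30 (2 higher, 7 lower; adjusted p = 0.283). For ybx1 the values were 343 ± 47.1 and 278 ± 33.8. The 58 cell cycle genes had a median of 0.07 (40 higher, 18 lower; adjusted p = 0.283). For rrm2 the values were 117 ± 38.5 and 68.3 ± 32.6 and for bub1bb 18.2 ± 4.56 and 27.8 ± 4.15. The 59 genes of chromatin and DNA methylation had a median of 0.10 (37 higher, 22 lower; adjusted p = 0.332). For hdac1 the values were 391 ± 56.0 and 477 ± 41.4 and for kdm6a 39.3 ± 10.3 and 55.2 ± 16.8. Only 3 genes of the gonad and sex list were measured, too few for the test, and among them nr5a2 was at 4.93 ± 1.48 and 6.61 ± 2.14. Apart from insm1a, 0 members of the lists in this and the preceding paragraph passed, over all genes or adjusted over the list alone. The authors' deposited table lists rrm2 (FDR 0.00122), col8a1a (0.0029), cldne (0.0286) and ascl1b (0.0493) as lower at an FDR below 0.05. It also called other members of these lists, among them ctslb of the hatching gland (0.00366) as lower and crygn2 and hbbe1.1 as higher.

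The spread between libraries was compared to ask whether offspring of starved fathers vary more. The median over genes of the log2 ratio of variances, starved over fed, was 0.10, a ratio of 1.07, and 53% of the 13680 genes varied more in offspring of starved fathers (two-sided exact permutation p = 0.630 over 924 arrangements). The log2 ratio was -0.06 without starved replicate 3, 0.26 without fed replicate 4, and 0.67 without fed replicates 4 and 5, which lowers the spread of the fed group by construction, since they were chosen for extreme scores. The median SD of log2 values was 0.49 in offspring of fed fathers and 0.52 in offspring of starved fathers (n = 6 each).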

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

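Within groups of 6 libraries, 144 sets of values (named genes, list scores, the share of the most abundant transcript and the reads) were searched for a library far from the others, by its gap to the nearest library over the range of the group. In 7 sets the gap exceeded Dixon's 95% critical value for 6 samples, where chance alone gives 1 in 20, or 7.2 sets, so the number of such sets is near what chance gives. All 7 were sets of offspring of starved fathers, and the cause was not tested. The sets overlap, so they are not independent.

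Among offspring of starved fathers, insm1a was lowest in replicate 1, at 10.8 against 16.1 to 17.9 in the others (gap 0.789 of the range on the log2 scale), and the lens crystallin gene crygn2 was lowest in replicate 4, at 8.80 (0.753). The homeobox gene msx1b was highest in replicate 5, at 7.89 (0.633), and dsg2.1 was highest in replicate 6, at 8.18 (0.631). The score of the amino acid and integrated stress response list was lowest in starved replicate 3, at -0.38 (0.738). The heat shock score was highest in starved replicate 2, at 0.46 (0.728), the library with the highest fosab value. The score of the 3 gonad and sex genes was lowest in starved replicate 3, at -1.41 (0.655).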

How the results depend on the processing

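Alternatives with a left-out pair of libraries, an estimated correlation with libraries left out or the code block, another pseudocount, a minimum mean value, quasi-likelihood with TMM or likelihood ratio tests on recovered reads, permutations of list scores and other thresholds for the authors' table were chosen after the data were seen. The 0 genes past the threshold stayed 0 with both pseudocounts, a minimum mean value of 5, an adjusted p below 0.1, a minimum log2 fold change of 1, each of the 12 libraries left out (lowest 0, highest 0), replicates 5 and 6 summed, edgeR's quasi-likelihood test (TMM, RLE, a stricter filter, code block), limma-voom and DESeq2. With the replicate block it was 39 in limma (8 higher, 31 lower) and 15 in edgeR's quasi-likelihood test (3 and 12), and 38 and 15 of these are among the 105 calls of the authors' deposited table. With the code block it was 1 in limma, and in edgeR's likelihood ratio test 73 with trended and 3 with gene-wise dispersion. Same-numbered libraries of both groups correlated between 0.07 and 0.32 in their deviations from the group means, not above 0.1 in every pair, so the numbers were not taken as a pairing. The mean was 0.174 for same and -0.035 for other numbers, and the best correlation of 10 of the 12 libraries was with their own number, a hint from the data. Same-numbered libraries also share a description code, and those of replicates 5 and 6 a letter after it, but the labels do not say what codes or letters mark. If they mark a shared clutch or day, the fits with a block would be the ones to read. In the 32 assignments that swap groups within numbers, the highest count besides the real one was 15 genes.

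Of the 3 called lists, 0 stayed called with an estimated correlation (adjusted p = 0.918 for each), with fry (0.849 each) and with exact permutation of library scores (0.833 each). Exact sign-flips of score differences in the replicate block (0.469 each) decide nothing, since 6 pairs are too few for 3 lists to pass after adjustment over 33. Without fed replicates 4 and 5, chosen for their scores, the yolk list was at 0.327 and the muscle list at 0.977, while ribosome biogenesis, cytosolic ribosomal proteins (median 0.09) and oxidative phosphorylation (0.14) were called higher and lens crystallins (-0.34) lower, but adjusted p = 0.995 for each with an estimated correlation. Starved replicates 4 and 5, which share the description codes of the removed libraries, stayed in. With each library left out, the number of called lists was 3 to 4, and adjusted p was 3.48e-12 to 0.000114 for yolk, 2.23e-12 to 0.00720 for muscle and 1.97e-06 to 0.0759 for ribosome biogenesis, the highest without starved replicate 4. With an estimated correlation 0 lists were called without any 1 library (smallest adjusted p 0.714 to 0.991). The replicate block and the code block each called 4 lists, lens crystallins being added (adjusted p = 0.0132 and 0.0157), and changed no other list call, but with an estimated correlation 0 lists were called (smallest adjusted p = 0.876 and 0.914). The log2 variance ratio was -0.06 to 0.26 with each library left out and 0.67 without fed replicates 4 and 5, a removal that lowers the fed spread by construction. The 105 calls of the authors' deposited table became 145 at an FDR below 0.1, 53 at an FDR below 0.01 and 40 with a log2 fold change of at least 1. The causes were not tested. Over 164 named genes and list examples, 4612 of 4685 repeats left the gene uncalled and 73 called it. Reversed calls could not occur, since 0 genes were called in the main comparison. Removing the replicate number from the spread gave no value, since residuals of the 2 groups mirror each other, and dropping the low-count filter was not run because the table was filtered before deposit. With 2950739 to 3934765 reads per library, small changes of genes at a few reads were not detectable.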

Other observations

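The lists of lysosomal and of immediate early genes, the tests of a later stage, of the amount of yolk, of the dispersion and of immediate early genes, the relations between list scores and the sorting of splits by replicates 5 and 6 were chosen after the values had been seen.

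Lysosomal genes beyond those named above followed the yolk list. A list of acid hydrolases and lysosomal membrane proteins was written after the lowest genes of the authors' deposited table had been seen, and members of the yolk list and the 4 named genes ctss2.1, acp5a, npc2 and spns1 were taken out. Of the 42 genes left, 35 had a lower mean in offspring of starved fathers, with a median log2 difference of -0.27 (camera, p = 6.85e-05; p = 0.167 with an estimated correlation). The list score was 0.14 ± 0.40 in offspring of fed fathers and -0.14 ± 0.18 in offspring of starved fathers (SD, n = 6 each, two-sided exact permutation p = 0.171). Of the 42, 3 were lower at an FDR below 0.05 in the authors' deposited table (Fisher's exact test p = 0.00223). These were fuca2 (-1.26, FDR 0.000568), psap (-0.78, FDR 0.00102) and ctsh (-0.79, FDR 0.0238). Since the list was written after genes of the same data had been seen, its p-values only describe the pattern. Over the 12 libraries the score followed that of the yolk list (Pearson r = 0.947, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 7e-05). Spearman's rho was 0.895 (permutation p = 0.00014, adjusted 0.00098). Pearson r was 0.894 without fed replicates 4 and 5, the 2 farthest from the median, 0.968 among fed and 0.921 among starved libraries, and 0.923 after centring on description codes.

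Scores of other lists were related too, though some relations weakened without fed replicates 4 and 5 or after centring on description codes. Of 7 relations computed, muscle scores rose with lens crystallin scores (Pearson r = 0.954, permutation p = 3e-05, adjusted 0.000105; Spearman rho = 0.867, permutation p = 0.0005, adjusted 0.00175). That r was 0.923 without fed replicates 4 and 5, 0.987 among fed and 0.960 among starved libraries, and 0.920 after centring on codes. Muscle scores fell with yolk scores (Pearson r = -0.866, permutation p = 0.00039, adjusted 0.00091; Spearman rho = -0.671, permutation p = 0.0195, adjusted 0.0334). That r was -0.701 without the same 2 libraries, -0.851 among fed and -0.868 among starved libraries, and -0.842 after centring. Pigment cell scores rose with muscle scores (Pearson r = 0.715, permutation p = 0.00933, adjusted 0.0122; Spearman rho = 0.657, permutation p = 0.0238, adjusted 0.0334). That r was 0.726 without the 2 libraries, 0.930 among fed and 0.807 among starved libraries, but -0.02 after centring on codes. Muscle scores fell with hatching gland scores (Pearson r = -0.752, permutation p = 0.00606, adjusted 0.0106; Spearman rho = -0.531, permutation p = 0.0796, adjusted 0.0796). They fell with somitogenesis and tailbud scores (Pearson r = -0.698, permutation p = 0.0105, adjusted 0.0122; Spearman rho = -0.559, permutation p = 0.0629, adjusted 0.0734), and with the share of the most abundant transcript (Pearson r = -0.592, permutation p = 0.0422, adjusted 0.0422; Spearman rho = -0.734, permutation p = 0.00835, adjusted 0.0195). For these 3 relations r was -0.356, -0.322 and -0.412 without fed replicates 4 and 5, -0.797, -0.835 and -0.726 among fed and -0.511, -0.42 and -0.312 among starved libraries, and -0.814, -0.603 and -0.47 after centring on codes.

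The lower yolk and higher muscle genes in offspring of starved fathers are the pattern most worth following. On values scaled to the bulk of genes, muscle scores followed those of lens crystallins over the 12 libraries (r = 0.954). This argues against the amount of yolk tissue, with the same embryo proper, as the only difference between libraries. It does not decide whether only that amount differed between the groups of fathers. Their muscle scores differed within the spread between libraries (two-sided exact permutation p = 0.268). Chance is not excluded: 17 of 100 splits of the libraries, the real one included, gave as large a difference of muscle and yolk medians (0.88, highest other split 1.64). The difference of muscle minus yolk scores was 0.87 ± 0.60 (SE) with all libraries and 0.31 standard errors (0.13 ± 0.41) without fed replicates 4 and 5, so it may rest on them. They were picked for their extreme scores, and leaving them out lowers it by construction. The same-numbered starved libraries stayed in, and starved replicate 4 also had a low muscle score (-0.55) and a high yolk score (0.44). This removal was therefore uneven between the groups and does not decide what the difference rests on. A later stage of the embryos of starved fathers at collection stays open, since lens crystallins were higher by 0.45 standard errors (0.24 ± 0.52) with all libraries and lower by 0.92 (-0.35 ± 0.39) without fed replicates 4 and 5, and an effect of the fathers' starvation stays open too.

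For the counts behind the comparison, 84 of 100 splits gave at least the real 3 lists in camera (highest other split 12), so chance is not excluded for the lists. For the 0 genes in limma the splits decide nothing, since any split gives at least 0 genes (100 of 100, highest other split 34).

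The 105 calls of the authors' deposited table stand against 0 in the tests without a block. A likelihood ratio test of edgeR with trended dispersion and the description codes as a block called 73 genes, all 73 among the 105, with log2 fold changes within 0.13 of the deposited ones over all genes, so the deposited table may come from a fit of this form. With gene-wise dispersion 3 of the 73 stayed called (4.11%), ctss2.1, acp5a and selenop2, and with the same block limma called 1 gene and edgeR's quasi-likelihood test 0. Limma with the replicate number as a block called 39 genes, 38 of them among the 105. That is fewer than the 73 with trended dispersion and more than the 3 with gene-wise dispersion. Whether the authors' calls rest on a dispersion that leaves out the spread of single genes is therefore not decided. Of the 48 splits of libraries within codes, 5, the real one included, gave at least 73 genes with the trended dispersion (highest other split 155), so chance is not excluded over them. The 4 others all set both libraries of replicate 5 against both of replicate 6, which share a code, and in the 32 splits that do not, the highest count besides the real one was 41. Whether these numbers mark a shared clutch or day is not said in the labels, so this part stays open, as does an effect of the fathers' starvation.

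The high fosab in offspring of starved fathers lay in replicates 2 and 5, which were picked by these values: without them the log2 difference was -0.26 standard errors (-0.12), so the pattern may rest on 2 libraries. Some other immediate early genes were high in the same libraries: ier2a was at 123 and 47.0 (3.13 to 28.9 in the other 10), ier2b at 67.7 and 43.2 (0.86 to 17.6), fosl1a at 46.9 and 18.5 (0 to 11.7) and btg2 at 167 and 129 (19.0 to 81.3). Others were not, among them klf2b at 6.60 and 11.7 (1.93 to 20.6 in the other 10). In the authors' deposited table klf2b was lower (-1.34, FDR 0.0225). Over 23 immediate early genes without fosab the median log2 excess over the other libraries was 1.29 in starved replicate 2, where 13 genes exceeded 1, and 0.48 (0.478) in starved replicate 5, where 8 did. A general rise of immediate early genes, such as handling of embryos before freezing could give, is therefore not decided for both libraries, and whether it differs with the fathers' feeding was not tested beyond the comparison of groups.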
